A study of Mus musculus with 8 samples.

How the data were processed

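RNA from dissociated lumbar dorsal root ganglia of mice was sequenced from its polyadenylated 3′ end (QuantSeq 3′ mRNA-seq REV, a kit whose reads start at the poly(A) tail and keep the strand). The labels give 4 naive and 4 injury libraries, taken at levels L4 to L6, 3 days after a crush of 1 sciatic nerve. Per the submitters' processing notes, bcl2fastq 2.17, STAR and HTSeq were used with GRCm38/mm10; versions of STAR and HTSeq are not given in the sources used here.

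The authors deposited a table of read counts per gene with 24060 rows, whole numbers that were not normalized. Of these rows, 27 carry a date in place of a gene name. They hold 0.133% to 0.164% of a library's counts, stayed in the library sizes and tests, and are not named. A further deposited table gives read counts for 243007 rows of genomic windows, of which 97.9% are 25 bases wide. How these windows were chosen, and how reads that map to several places were counted, is not given in the sources used here.

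The window rows fall into a block per strand. Of the windows, 20990 are listed in both blocks and 201027 are listed once, each of the latter with a repeat class. The strand column equals the block for windows listed once, but marks all 20990 windows listed in both blocks as plus; the block was taken as the strand for these too. In the plus block, with 97.1% of their counts, 98.8% of the counts lay on a plus gene and 16.9% on a minus gene. In the minus block these shares were 99.2% and 99.6%, which does not settle its strand. GENCODE vM21 genes on the same build, extended by 1000 bases past their 3′ end, gave 22142 windows on the strand of exactly 1 gene. These are called sites here, and 19313 of them lie in the plus block, so the site usage of genes on the minus strand was hardly tested. Over 2159 genes with at least 800 site counts, their sum was a median 98.9% of the gene count. Overlapping repeat windows were merged into 177005 loci, each represented by its window with the most counts. Coordinates of sites are as the deposited table gives them, with no statement of whether it counts from 0 or 1.

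Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, group as the only term) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Gene lists, 28 in all and fixed beforehand, were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated. Of their 600 entries, 598 were found in the table, 1 of them under an older symbol. Site usage was tested with diffSpliceDGE and Simes p-values per gene, over sites that passed filterByExpr and held at least 5% of the gene's counts. Usage is a site's percent of the counts of the gene's kept sites. For the GC correction, each gene's mean was fitted with the count-weighted offset of its own sites, since the package's function takes that of the first site for every gene. For genes and sites, the correction smooths each library's deviations from the mean over all libraries against GC content. It therefore also removes a difference between the groups that follows GC content. Sites with no GC value were left uncorrected. Direction compares the most distal with the most proximal kept site after adding 0.5 to each count. Repeat loci were tested 1 by 1 with the quasi-likelihood test, scaled by the library sizes and TMM factors of the gene table. Sums per repeat class were compared by a two-sided exact permutation test over all libraries, and within pairs by an exact test over the signs of the 4 differences. A read may be counted at several loci, so these sums are not numbers of reads.

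The genes named are Atf3, Gap43, Sprr1a, Jun, Gal and Npy; the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 3 that changed the same way in every same-numbered pair; and the 2 members of each list with the smallest p, or 3 in each of 5 lists. For site usage they are the 8 genes with the smallest p and up to 6 called members of the list of genes with described poly(A) isoforms. Other genes named are list members past the test, or genes chosen after their values were seen, which is said where they appear. The values of some genes that this rule takes are not reported here.

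The design text says that injured and naive ganglia came from each of 4 mice, so same-numbered libraries were taken as pairs. The correlations of their deviations from the group means were 0.13, 0.22, 0.05 and 0.17. In pairs 1, 2 and 4 each library matched its same-numbered partner best, but not in pair 3, so the pairing is an assumption. The planned test has no block for the mouse; a blocked value is printed where it changes a call or moves a count by over 1.5 times.

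Each test was tried on simulated counts with 200 changed genes or loci. For genes (13770 tested), 86.4% of 4-fold, 65.7% of 2-fold and 23.9% of 1.5-fold changes were recovered. For site usage (1316 genes in the simulated table), these shares were 77.3%, 28.4% and 5.97%. For repeat loci (18331 tested), 34.8% of 4-fold, 2.99% of 2-fold and none of the 1.5-fold changes were recovered after adjustment. The median recovered log2 change of 4-fold loci was 1.97, and 4.50% of the simulated loci without a change had an unadjusted p under 0.05. Recovery after adjustment depends on how many rows change. The data gave calls for 2454 genes, 8533 repeat loci and 8 genes in site usage, against 200 changed in each simulation. These shares are therefore not the recovery in the data.

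Alternatives chosen before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters on low counts and site shares, the gene F test, the mouse as a block, leaving out each library, leaving out sites before an A-rich stretch (8 A in 10 bases within 50 bases, on transcript sequence), and an adjusted p under 0.01. All alternatives for repeat loci, a per-library correction for the GC content of the last 100 nucleotides, leaving out 3 libraries low in AT-rich 3′ ends, and leaving out sites with a repeat class or in the minus block were chosen after seeing the data.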

Results

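The series asks how a sciatic nerve crush changes alternative polyadenylation in the sensory ganglia whose axons run in that nerve. It compares 4 injury with 4 naive libraries of mouse L4 to L6 dorsal root ganglia, 3 days after the crush. Gene counts summed to 20736599, 20705879, 17459084 and 22092535 in naive libraries 1 to 4, and to 23317451, 28950551, 21521807 and 16539644 in injury libraries 1 to 4. The ribosomal RNA precursor Rn45s took 4.16% to 6.49% of them. Values below are CPM, counts scaled to library size, as mean ± SD with n = 4 per group, and adjusted p-values come from edgeR's quasi-likelihood test unless another test is named.

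Injured ganglia carried far more RNA of the genes of the axotomised sensory neuron. Of the 39 measured genes of the injury response and regeneration list, 36 rose and none fell (37 rose when adjusted over the list alone), with a median log2 fold change of 2.47. Atf3, a stress-induced transcription factor, went from 60.4 ± 7.88 to 329.2 ± 30.02 CPM (log2 fold change 2.45, SE 0.11, adjusted p = 1.89e-08; GRCm38 chromosome 1, 191170296 to 191218039). The neuropeptide gene Gal (chromosome 19, 3409915 to 3414544) rose from 38.0 ± 3.09 to 864.5 ± 119 CPM, a log2 fold change of 4.51 (SE 0.12, adjusted p = 4.08e-10). Npy, another neuropeptide gene, went from 1.19 ± 0.337 to 158 ± 37.8 CPM, and Sprr1a from 1.10 ± 0.748 to 625 ± 117 CPM. Flrt3 (log2 fold change 3.26, SE 0.09) and the transcription factor Sox11 (3.00, SE 0.09) had the smallest p after Gal. Gap43, a growth cone protein gene, rose by 1.44 (SE 0.12) and Jun by 0.54 (SE 0.07) on the log2 scale. Cckbr, Slc6a4, Crh and Ecel1 were among the 6 largest rises. Their naive libraries together held 5, 14, 20 and 66 counts, against 2623, 4003, 3364 and 8205 in the injury libraries.

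**Figure D1:**
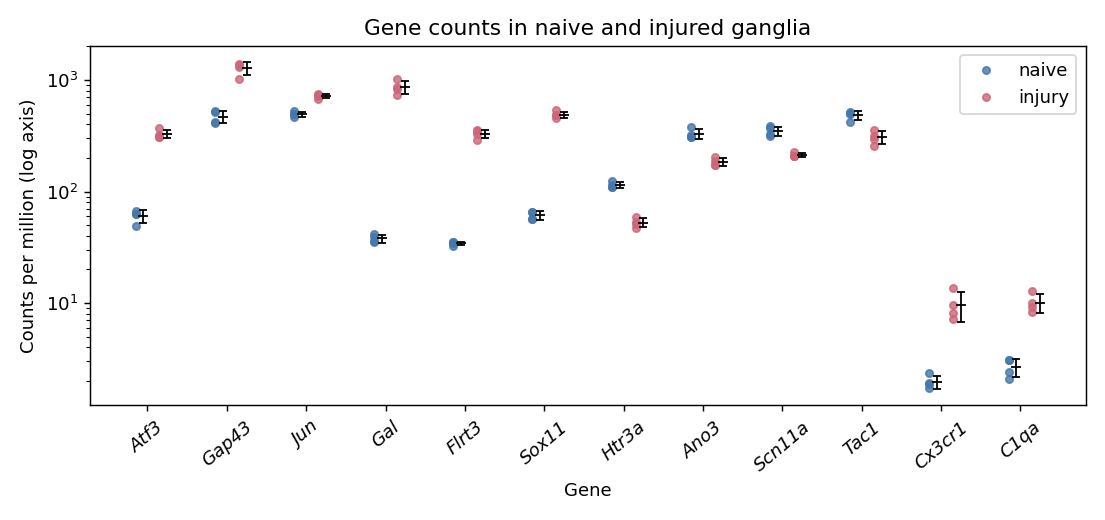
CPM on a log axis for 12 genes, with a point per library (4 naive, 4 injury) and the group mean ± SD beside the points. Atf3, Gal, Flrt3 and Sox11 lie higher in every injury library, and Htr3a, Ano3, Scn11a and Tac1 lower.

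Of 13770 genes tested, 2454 changed, 1387 higher and 1067 lower in injury. Leaving out naive replicate 3 brought the lower calls to 689. Among transcription factors linked to neuronal injury, 15 of 30 rose, which include Fosl1 (log2 fold change 2.62), Nfil3 (1.66) and Atf4, and none fell (2 with the mouse as a block).

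Receptor and channel genes of sensory neurons were lower. In that list 25 of 37 measured members fell and none rose (27 fell and 1 rose when adjusted over the list alone). Htr3a, a serotonin-gated channel subunit, went from 114 ± 6.47 to 52.6 ± 5.03 CPM (log2 fold change -1.12, SE 0.09, adjusted p = 4.78e-06). Ano3 had a log2 fold change of -0.84 and the sodium channel gene Scn11a one of -0.71. In the list of non-peptidergic nociceptor markers 8 of 14 fell and 1 rose, with Gfra2 at -0.68. Among markers of large-diameter neurons 6 of 16 fell (10 with the mouse as a block) and 1 rose; Cntnap2 had a log2 fold change of -0.47 and Necab2 of -1.53. In the peptidergic list 4 of 8 fell, which include Tac1 (-0.65), while Adcyap1 rose (1.48). Pan-neuronal genes went both ways, with 4 of 18 higher, Stmn2 (0.88) and Tubb3 (0.55) among them, and 2 lower. The 6 largest falls were Vstm2b, Plac8, Htr3b, Glb1l2, Hoxb6 and Bambi, with log2 fold changes from -1.88 to -1.47. Vstm2b lost its call without naive 3, naive 4, injury 2 or injury 3 (adjusted p up to 0.0787), and Plac8 without naive 3, naive 4, injury 1 or injury 2 (up to 0.130) and with DESeq2 (0.0746).

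Of the macrophage markers 8 of 24 rose and 16 did not pass the test, and the list was not called with an estimated correlation (adjusted p = 0.716). Cx3cr1 went from 1.96 ± 0.273 to 9.66 ± 2.93 CPM, C1qa from 2.68 ± 0.493 to 10.1 ± 1.94 CPM and C1qc from 1.76 ± 0.972 to 7.997 ± 2.91 CPM. Of the members that did not pass, 7 had a log2 fold change under 0, which include Ptprc (-0.89, adjusted p = 0.290) and Lyz2 (-0.80, 0.255), both chosen after their values were seen. All 8 neutrophil and lymphocyte markers were lower in each of the 4 pairs, and 7 of them passed the test with the mouse as a block. Without the block 1 passed, the neutrophil granule gene Ltf (log2 fold change -1.24, adjusted p = 0.0419), and 5 when adjusted over the list alone. Ltf lost its call without naive 3, naive 4, injury 1 or injury 2, with adjusted p up to 0.144. S100a8, with a log2 fold change of -1.27, had an adjusted p of 0.0644, and of 6.56e-05 with the mouse as a block. The red cell gene Slc4a1 did not pass the test (adjusted p = 0.116) but did with the block (0.00289), under which 3 of the 4 red cell genes were lower.

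Among genes of injured or repair glia 5 of 14 rose, Gap43, Tnfrsf12a (2.28), Vim, Ncam1 (0.40) and Bdnf. At least Gap43, Vim and Bdnf are known in neurons too, and counts of ganglia do not tell which cells changed. Of satellite glia markers 1 of 16 rose, the glutamine synthetase gene Glul (0.63), and of myelin genes 1 of 18, Mal (0.47), which lost its call without naive 2, 3 or 4 or injury 1 or 3 (adjusted p up to 0.0848). In the fibroblast list 2 of 20 rose, Slc2a1 (1.05) and Apod (0.92). None of the 16 endothelial, 12 mural cell, 4 red cell or 3 skeletal muscle genes measured was called by edgeR; with an unadjusted p under 0.05 there were 0, 2, 1 and 0. Limma-voom called 0 of them, and DESeq2, which tests more genes, called 1 gene of the skeletal muscle list.

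Cholesterol synthesis and uptake genes rose in 6 of 20 cases, with Hsd17b7 at a log2 fold change of 1.71 and Mvd at 0.73. In the unfolded protein and integrated stress response list 6 of 19 rose, Chac1 and Atf4 among them, and none fell (2 with the mouse as a block); Chac1 went from 11.7 ± 2.30 to 52.8 ± 7.49 CPM. Ribosomal protein genes rose in 5 of 24 cases (3 with the block), Rps3 by 0.50 and Rpl18 by 0.39. Complement and cytokine genes had 4 of 19 higher, with C4b at 1.20 and Ccl7 at 1.84, and 1 lower (2 with the block). Of the cell cycle list only Cenpf of 17 passed the test (2.74), against 2 genes with the block. Interferon-stimulated genes had 1 of 18 lower, a call that was lost without naive 1, 3 or 4 or injury 2 or 3. Immediate early genes, which rise on tissue dissociation, had 2 of 20 higher, Atf3 and Dusp1, and 2 lower, Fosb (-0.54) and Hspa1b (4 lower with the block). Among respiratory chain subunits 1 of 26 rose, Sdhb (0.40; adjusted p = 0.0515 without naive 3), and 2 fell; Ndufb3 (-0.35) was not called after the GC correction (adjusted p = 0.116).

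Of 23 core cleavage and polyadenylation factors 2 rose, Sympk (log2 fold change 0.65, SE 0.13) and the poly(A) polymerase gene Papola (0.28, SE 0.08); Papola lost its call without naive 1 or 4 or injury 1, 2 or 4 (adjusted p up to 0.0745). Pabpc1 had 0.27 (adjusted p = 0.0567, and 0.0353 with the mouse as a block). Among RNA-binding proteins known to influence poly(A) site choice 6 of 30 rose, with Rbfox2 at 0.54, Srrm4 at 1.32 and Elavl3 at 0.42, and 2 fell, Cpeb1 and Celf2. Neither of these was called with the block (adjusted p = 0.0513 and 0.0776), while Rbfox3 then was (0.0479, against 0.0512). Of genes with described poly(A) isoforms in neurons 11 of 34 rose, Atf3 and Gap43 first by p, and 2 fell (5 with the block).

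**Figure D2:**
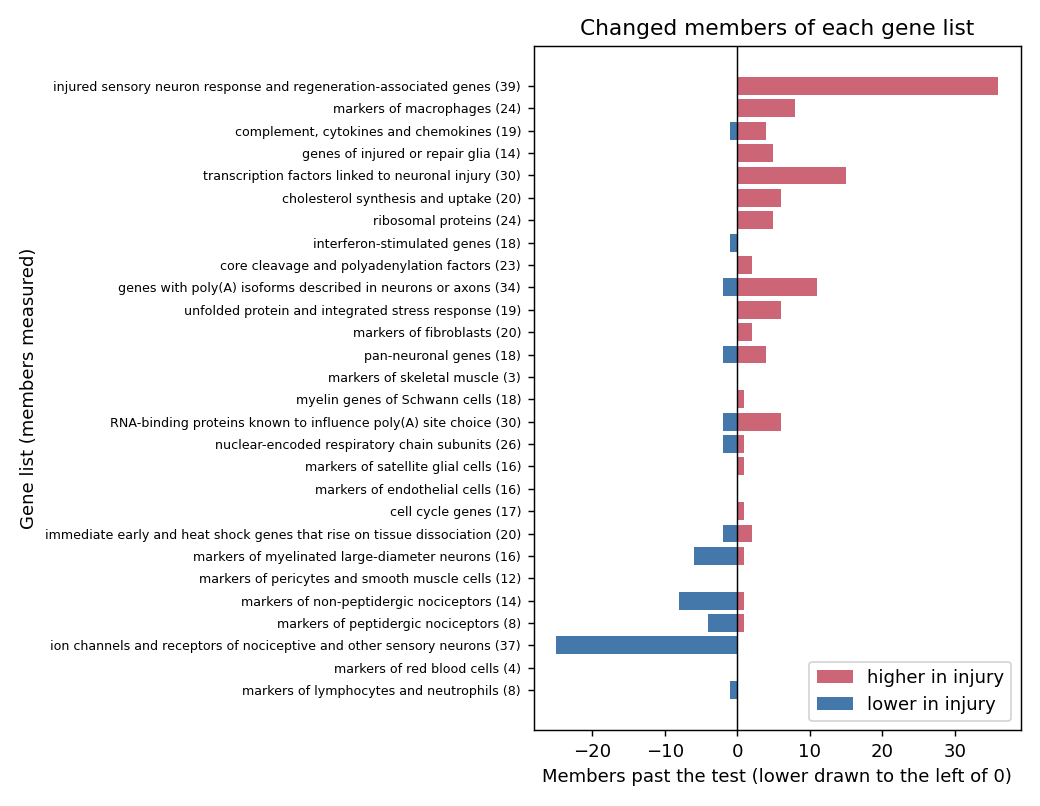
Members of each of the 28 gene lists past the test, as bars to the right of 0 for higher and to the left for lower in injury, with the number of measured members in brackets. The regeneration list has 36 members higher and the list of channels and receptors 25 lower.

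By camera with the preset correlation, 11 of 28 lists changed, 7 up and 4 down. With an estimated correlation 3 remained called: regeneration (adjusted p = 6.33e-06), injury transcription factors (0.0203) and channels and receptors (0.0162). The calls of the other 8 were lost, with an adjusted p of 0.260 for injured glia, 0.268 for genes with poly(A) isoforms, 0.408 for non-peptidergic markers, 0.600 for cholesterol, 0.669 for large-diameter neurons, 0.697 for neutrophils and lymphocytes, 0.697 for ribosomal proteins and 0.716 for macrophages. Splits of the libraries that part 2 of the 4 pairs gave up to 13 lists with the preset correlation, so these calls are not read alone. The member counts above are no tests of a list. They stand beside all genes, of which 1387 of 13770 were higher and 1067 lower. In the fibroblast, satellite glia, myelin, cell cycle and cleavage factor lists the share higher was not above that of all genes. The same holds for the immediate early, respiratory chain, non-peptidergic and large-diameter lists. The share lower was not above that of all genes in the interferon, complement and cytokine, respiratory chain, RNA-binding and poly(A) isoform lists. With the mouse as a block, the red cell list was called as lower with the preset correlation (adjusted p = 0.00805, against 0.245); without the block, an estimated correlation gave an adjusted p of 0.716. Median, mean and test differed in sign for satellite glia, myelin, cell cycle and the RNA-binding list, none of which was called.

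Libraries naive 2, injury 2 and injury 3 held fewer counts of genes with AT-rich 3′ ends than the others of their groups. Genes under 20% GC in the last 100 nucleotides had median deviations from the group mean of -0.17, -0.29 and -0.38 on the log2 scale in these libraries, and of 0.34 and 0.36 in injury 1 and injury 4. Among the 739 genes under 25% GC, 40 were called higher and 71 lower, or 43 and 109 with the mouse as a block. After the GC correction these were 74 and 57, and 73 and 70 with the block. The correction also removes any difference between the groups that follows GC content, so these counts cannot tell a bias from an effect of injury.

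Few of the genes tested changed in the use of their poly(A) sites. Of 1355 genes with at least 2 kept sites, 1346 of them on the plus strand, 8 were called, 3 toward the distal and 5 toward the proximal site (exact binomial test, two-sided, p = 0.727). The direction compares the outermost sites only: in Klhl24, counted as distal, the most distal site went from 29.6% to 22.2% of the counts, and in Zfp318, counted as proximal, the most proximal from 29.5% to 22.3%, as an inner site gained in both. Without adjustment 59 genes had p under 0.05, against 82 with the mouse as a block and 215 with limma-voom. Chance gives about 1 in 20 of the 1355 genes, a share that 59 does not exceed and that 82 and 215 do. With the mouse as a block 4 of the genes were called, with limma-voom 17 and with the gene F test 20. Of 5 tested genes with described poly(A) isoforms none was called by edgeR, also when adjusted over the list alone; 0 had an unadjusted p under 0.05, and limma-voom called 0. In the simulation most changes of 2-fold or less in a site's counts were not recovered.

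In Mettl7a1 the proximal 3′ UTR site (chromosome 15, 100313303 to 100313328) went from 5.87% ± 1.00 to 20.4% ± 4.91 (SD, n = 4 each) of the gene's counts. In Eml4 a site downstream of the annotated gene (chromosome 17, 83481317 to 83481342), which carries the classes simple repeat and B2, went from 16.2% ± 6.92 to 63.2% ± 9.94. Klhl24 gained use of a 3′ UTR site of class B2 (chromosome 16, 20128146 to 20128171), from 17.8% ± 3.21 to 41.9% ± 7.70. In Zfp318 a B2 site in the 3′ UTR (chromosome 17, 46416429 to 46416454) went from 3.74% ± 2.29 to 12.0% ± 3.397. It did not gain in pair 3, with 7.09% in naive 3 and 6.99% in injury 3. In the gene model Gm20388 an intronic B2 site (chromosome 8, start 123136240) went from 41.5% ± 7.16 to 79.4% ± 5.09. The other kept site of Gm20388, also intronic, starts at 123836681. Whether both belong to 1 transcript was not tested, so a choice between its poly(A) sites is not shown. Bri3bp gained a site downstream of its annotated end, from 6.25% ± 1.86 to 20.2% ± 2.10. The proximal sites of Cds2 and Procr, both in the 3′ UTR, went from 15.4% ± 0.437 to 25.3% ± 6.47 and from 50.03% ± 6.83 to 75.1% ± 3.92. The calls of Zfp318, Gm20388, Cds2 and Procr were lost with the mouse as a block (adjusted p = 0.0826, 0.0736, 0.0736 and 0.115). After the GC correction the call of Cds2 was lost (adjusted p = 0.899), with the log2 change of its proximal site relative to the gene going from 0.71 (SE 0.14) to 0.37 (SE 0.15), and that of Procr (0.103), with its distal site going from -1.03 (SE 0.22) to -0.89 (SE 0.20). With the block and the GC correction together Gm20388 kept its call (0.0474), though it has no site with a GC value. Without sites that carry a repeat class 3 genes were called, Mettl7a1, Bri3bp and Cds2. The gained sites of Klhl24 and Zfp318 lie before an A-rich stretch, as do the distal sites of Cds2 and Procr and 2 sites of Eml4, and the gained sites of Eml4, Bri3bp and Gm20388 could not be searched, so priming inside transcripts is not excluded there. Without sites before such a stretch 3 genes were called, Mettl7a1, Bri3bp and Gm20388; Klhl24 (adjusted p = 0.9999) and Zfp318 (0.354) were not, and Eml4, Cds2 and Procr had too few sites left to test. Bri3bp lost its call without naive 2 or 3 (adjusted p = 0.0565 and 0.0687), and Klhl24 without naive 4 (0.0654). Leaving out single libraries also ended the calls of Zfp318, Gm20388, Cds2 and Procr, with adjusted p up to 0.278, 0.237, 0.392 and 0.284. Without naive 2, injury 2 and injury 3 together, Bri3bp, Zfp318, Cds2 and Procr were not called (adjusted p = 0.295, 0.135, 0.150 and 0.171). Mettl7a1, Eml4, Klhl24 and Gm20388 then kept their calls (adjusted p up to 0.0306).

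Counts at repeat loci rose, above all at B2 elements, short interspersed repeats of the mouse genome. Summed over B2 loci, they went from 88637 ± 6083 to 191462 ± 17860 CPM of gene counts (SD, n = 4 each), higher in each injury library than in each naive one. The exact permutation p of 0.0286, two-sided and without the pairs, is the smallest that 4 against 4 libraries can give, and 0.0603 after adjustment over 19 classes; within the 4 pairs the smallest possible exact p is 0.125. Of 11991 B2 loci tested 7272 rose and 16 fell, with a median log2 fold change of 1.32. Alu loci, the class that holds mouse B1 elements, rose in 782 of 3177 cases and fell in 18, with a median of 0.62. The medians were 0.66 for scRNA loci, 0.08 for L1 and -0.12 for ERVK loci. In all, 8533 of 18331 loci changed, 8393 higher and 140 lower. Scaled by TMM over the loci themselves, which sets their typical change near 0, 2071 were higher and 1823 lower (1829 and 462 of B2, 181 and 388 of Alu), so the rise is one relative to gene counts. Which locus a read came from is uncertain: 5 B2 loci on 4 chromosomes each held between 276473 and 276874 counts over all libraries.

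**Figure D3:**
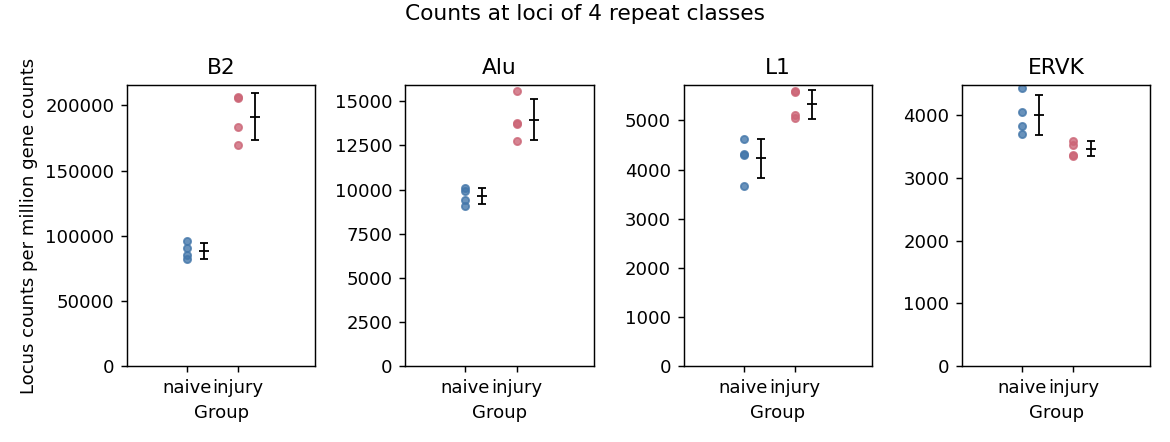
Counts at loci of 4 repeat classes, as CPM of gene counts, with a point per library (4 naive, 4 injury) and the group mean ± SD beside the points; axes start at 0. The B2 mean is 88637 in naive and 191462 in injury libraries.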

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

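The test of B2 against Alu counts, the test by library depth, the test of shared counts, the test of B2 sites over all tested genes, the tests of the GC correction on Mettl7a1, Klhl24 and Zfp318, and the splits for genes and for lists with the preset correlation were chosen after the values they measure had been seen. So were the comparison of the splits and of the B2 to Alu ratio by mouse pairs and the decision to leave transcripts of the gene open for B2 loci; bounds set beforehand, on all 35 splits for site usage and repeat loci and on the median by locus, had been met.

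Counts at B2 loci rose in injured ganglia. A higher yield of every A-tailed repeat would keep the ratio of B2 to Alu counts. Its log2 value was 3.11 to 3.36 in the naive and 3.45 to 3.91 in the injury libraries, with means 0.57 apart. All 4 pairs differed in that direction, by 0.72, 0.09, 0.68 and 0.80. The sums of both classes thus rose unequally, though pair 2 differed little and 4 pairs give no exact p under 0.125. The sums also take in loci on a gene's strand. There the median log2 fold change was 0.32 for Alu and 1.18 for B2 loci, against 0.84 and 1.36 outside genes. Transcripts of genes and reads counted at several loci may both enter the ratio, so it does not decide on yield. Whether few reads were counted at many loci stays open, since joining loci with like counts took in 2.96% of B2 loci. Transcripts of the gene that holds a locus stay open for the same reason: 9006 B2 loci on no gene's strand had a median log2 fold change of 1.36 (quartiles 0.90 and 1.92), but that bound assumed that a read is counted at the locus it came from, and 5 loci on 4 chromosomes held 276473 to 276874 counts each. The real split called 8533 loci and the others 0, but 8 splits part all 4 pairs, too few for a share under 0.05 (1 of 8 is the real one); a change of B2 RNA with injury is a hypothesis that remains beside the counting of reads.

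AT-rich 3′ ends were low in naive 2, injury 2 and injury 3. Within 400 genes with sites at least 10 GC points apart, the low-GC site was lower in each of these libraries, with upper bounds of the 95% bootstrap intervals at or under -0.0613, consistent with a bias by GC content. Depth is argued against, because injury 1, with 23317451 counts, lies between injury 2 and injury 3. The trend leaves single genes unaccounted for: Crtc2, chosen after its values were seen, had 32.9 and 33.7 CPM in injury 1 and 4 but 0.425 and 0.0483 in injury 2 and 3. No biological explanation was tested.

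Site usage changed in 8 genes, of which 4 gained a B2 site, while 61 of the 1355 genes tested have one (Fisher's exact test, p = 0.000228). Fisher's test was chosen after these genes had been seen, so its p is no independent support. B2 reads counted at a site may account for these 4 gains, but over all 65 B2 sites the median log2 usage change was 0.0497 (95% bootstrap interval -0.01 to 0.16), which decides neither way. Over the 61 B2 sites of genes that were not called it was 0.024 (-0.037 to 0.149). Loss of reads at AT-rich sites stays open for the set: the lower-GC site fell in 80% of the 5 called genes with a GC value (exact 95% interval 28.4% to 99.5%). Mettl7a1 and Klhl24 were picked because they kept their calls after the GC correction with and without the block (adjusted p up to 0.0377). That outcome is therefore no test of a smooth GC trend in each library. Without the block, the correction brought their log2 changes from 1.78 (SE 0.19) to 1.46 (SE 0.20) and from 1.23 (SE 0.21) to 1.04 (SE 0.22). It thus took away part of each change. Among the injury libraries, both gained sites were used most in injury 2 and injury 3, so a GC effect stays open for these genes. For Zfp318 the correction is no test of a smooth GC trend. Its 4 kept sites lie between 31% and 35% GC, so the correction could hardly move their usage. Its change with the block was 1.79 (SE 0.37) before and 1.78 (SE 0.39) after the correction. With both, Zfp318 was not called (adjusted p = 0.115). The trend stays open for Cds2 and Procr, which lost their calls. Their changes went from 0.71 (SE 0.14) to 0.37 (SE 0.15) and from -1.03 (SE 0.22) to -0.89 (SE 0.20). It also stays open for Eml4, Bri3bp and Gm20388, with sites of no GC value. Among the 8 splits that part all 4 pairs the real one called 8 genes and the highest other 0, but 8 splits are too few for a share under 0.05; of the other splits, which part 2 pairs or none, the highest called 1 gene.

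A sample stood apart from the other 3 of its group in 16 of 232 groups tested; chance gives about 1 in 20 groups. Naive 2 had 2569 CPM on the strand of no gene and 2425 at ERVL-MaLR loci. Naive 3 had 417 CPM of Tac1, 365 CPM of Rbfox2, 53.8% at the Eml4 site starting at 83480307, and 16.01% and 83.99% at the Cds2 sites. Naive 1 had 1.24 CPM of Mylpf. Injury 1 had 224 CPM of Scn11a and injury 2 had 4.32 CPM of Mcm5, 71.9% and 28.1% at the Gm20388 sites and a log2 ratio of B2 to Alu of 3.45. Injury 3 had 30.9 CPM of Sympk, 748 CPM at hAT-Charlie loci and 6.99% at the Zfp318 B2 site.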

How the results depend on the processing

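Alternatives for repeat loci, the GC correction, leaving out naive 2, injury 2 and injury 3, and leaving out sites with a repeat class or in the minus block were chosen after seeing the data. Of 63 named results past the threshold, 15 lost the call or changed direction under some alternative; the cause was not tested. At an adjusted p under 0.01, genes changed were 1265, 830 higher and 435 lower, since fewer pass a stricter threshold. Leaving out each library gave 1738 to 2438 genes, 1049 to 1356 higher and 689 to 1082 lower, and 8 to 12 lists; an estimated correlation gave 3 lists. Without the 3 libraries low in AT-rich 3′ ends 2317 genes and 9 lists changed.

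Genes with changed site usage ranged from 3 to 7 when each library was left out (2 to 4 distal, 1 to 4 proximal). They were 17 with limma-voom (7 distal, 10 proximal), 20 with the gene F test (7 and 13), 4 with the replicate block (1 proximal), 6 with the GC correction (3 and 3), 5 with the replicate block and GC correction (3 and 2), 3 without sites before an A-rich stretch (1 and 2), 3 without sites with a repeat class (1 and 2), 5 without the 3 libraries (3 proximal), and 3 at an adjusted p under 0.01 (1 proximal). Sites of at least 1% gave 3 proximal. The distal less proximal change of Klhl24 reversed to -0.12 without injury replicate 3 and to -0.21 without the 3 libraries, that of Zfp318 to 0.84 without sites with a repeat class, and the log2 fold change of Pvalb to 0.0047 without naive replicate 4. When each library was left out, Pvalb ranged from -0.29 to 0.0047 and Klhl24 from -0.12 to 0.42.

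Repeat loci changed were 3894 with TMM over the loci (2071 higher, 1823 lower), 13380 with overlapping windows kept apart (13060 and 320), where more rows are tested, and 38 lower at an adjusted p under 0.01. Leaving out each library gave 7255 to 8659, with 7128 to 8544 higher and 102 to 128 lower. The block for the mouse gave 2633 genes and 12 lists, and changed no other call of a gene named in the results than those given there.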

Other observations

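The test of the splits with an estimated correlation was chosen before its result was seen; the other splits are named with the flagged results.

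Alu loci showed a split by context that B2 loci showed less. On the same strand as a gene, 1235 Alu loci had a median log2 fold change of 0.32, against 0.82 for 736 loci on the opposite strand and 0.84 for 1206 outside genes. B2 loci had medians of 1.18, 1.35 and 1.36 in these contexts. Whether the contexts differ was not tested. L1 loci had medians of 0.0034 on a gene's strand and 0.12 outside genes. The class sums of 9 of 19 classes parted the groups in full, 7 higher in each injury library, which include L1 (4226 to 5328 CPM of gene counts), L2 (3286 to 4168) and scRNA (543 to 957), and 2 lower, ERVK (3998 to 3458) and hAT-Charlie. Each has the same exact permutation p. A class sum need not show the typical locus. Of 38 L2 loci tested 4 were called higher and 2 lower, with a median log2 fold change of -0.09. Of 313 L1 loci 18 were called higher and 9 lower. ERVK, lower in sum, had 22 of 489 loci called higher and 13 lower. Of 136 scRNA loci 37 were called higher and 0 lower. The sum of hAT-Charlie loci went from 983 ± 45.0 to 712 ± 23.9 CPM of gene counts (SD, n = 4 each; exact permutation p = 0.0286, two-sided and without the pairs, the smallest possible, and 0.0603 adjusted over 19 classes; within pairs 0.125). Of its 58 loci tested 4 were called higher and 7 lower.

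Same-numbered libraries were taken to come from 1 mouse, and 8 of the 35 splits of the libraries part all 4 pairs, too few for a share under 0.05. Among these 8, 1 split, the real one, gave as many genes (2454; highest other 0), as many lists with the preset correlation (11; highest other 9) and as many with an estimated one (3; highest other 0). The other splits part 2 pairs or none and called 0 genes. For lists with the preset correlation, 6 of all 35 splits gave at least 11, with 13 the highest of the others. With an estimated correlation 2 of 35 splits gave 3 lists: the real one and the split of replicates 1 and 2 against 3 and 4, which parts no pair and points to a structure between replicates.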
